A study of Mus musculus with 6 samples.

How the data were processed

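RNA was taken from 3 non-induced and 3 induced samples of the i660BM line with a Qiagen column kit, and stranded mRNA libraries were made, per the labels' protocols. The labels do not say whether the 3 libraries of a group came from separate cultures, so the authors' p-values may measure technical spread. Trim Galore 0.2.8.1, TopHat2 2.0.9, Cufflinks and Cuffdiff 2.1.1 and the mouse build mm10 are named in the submitters' processing notes. The gene annotation, and whether the counting used strand, are not given in the sources used here.

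The deposited table is a Cuffdiff gene comparison with 23793 rows. It holds 1 FPKM value per gene and group, made by the authors, and these values were used as deposited. It also holds the authors' log2 fold change, a test statistic (a score with no fixed range), a p-value and a q-value, all deposited by the authors. The authors had tested 10657 rows. They had not tested 13135 rows, and they marked 1 row as having too many fragments, so its listed value of 0 is a failed estimate. Other values of 0 can also be failed estimates, and a gene is therefore described as listed at 0. Values just above 0 in untested rows can be failed estimates too, and they do not show that a gene was absent. In 524 rows the deposited fold change was a spreadsheet error mark, and in each of these the induced value was 0. Symbols of 26 rows had been turned into dates, 14 of them tested and 4 called, and 202 rows carried several symbols. The deposited q-values were recomputed from the p-values by the Benjamini-Hochberg method over the 10657 tested rows and differed by at most 5.15e-07. The smallest p-value was 5e-05, shared by 1855 rows, which gave a smallest q-value of 0.000287. The deposited fold change differed from the ratio of the FPKM values by more than 0.01 on the log2 scale in 16 of 13193 rows, by at most 0.167.

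The file gave group values only, so no test per gene was made in this work. A gene is said to be called, to rise or to fall where the authors had tested it and the deposited q-value was under 0.05. Cuffdiff's statistic was read as the log fold change divided by its standard error, so the ratio of log2 change to statistic is given as an implied standard error. The table does not state that relation. The median implied standard error was 0.151 over tested rows. Depth was estimated from FPKM multiplied by transcript length for genes with 1 annotated transcript of at least 1 kb. The lowest values lay on steps worth 1 fragment, 0.00838 in non-induced and 0.00831 in induced cells, and 68.7% and 62.4% of values up to about 4 fragments lay within 0.15 of a whole number, against 30% for evenly spread values. The depth is therefore approximate, and the depth of single libraries is unknown.

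Coordinates were taken from the GENCODE M21 annotation of the same build, because the locus in the file covers a bundle of up to 50 rows. Of 10082 tested symbols found once there, 99.9% had a file locus that overlapped the annotated gene. Of the tested rows 2244 share a locus with another row, Zeb2, Zeb2os and Rag2 among them, and fragments of overlapping or antisense genes can have been split between them. Near-identical copies at separate loci can share fragments too, and leaving out shared loci does not address these. From general knowledge this could affect Vpreb1 and Vpreb2, Lyz1 and Lyz2, Csf2rb and Csf2rb2, the Ms4a6, Gimap, Oas and histone families, and genes with processed copies such as Gapdh and Eno1.

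Before the data were examined, 33 gene lists were fixed. They covered myeloid receptors and signalling adaptors, phagocyte NADPH oxidase, macrophage and granulocyte markers, myeloid transcription factors, B lineage transcription factors, ETS family factors, pre-B cell receptor and recombination, immunoglobulin light chain, B cell receptor signalling, and genes described as PU.1 or SPI-B regulated. Further lists covered IL-7 receptor signalling, S phase, mitosis, cell cycle inhibitors and p53 targets, MHC class II, interferon response, Toll-like receptors and NF-kB, integrins and chemokine receptors, lysosome and cathepsins, mitochondrially encoded genes, oxidative phosphorylation, the ATF4 response, glycolysis and hypoxia, cholesterol synthesis, and immediate early and heat shock genes. Marker lists covered T cells, NK cells, the erythroid and megakaryocyte lineages, mast cells and basophils, dendritic cells, stromal cells, plasma cells, and mature and immature B cells. Each list with at least 5 tested members was compared with the other tested genes by a two-sided Fisher's exact test per direction. The p-values were adjusted by the Benjamini-Hochberg method over 52 tests. The test treats genes as independent, and an estimated correlation between genes could not be computed from group values, so its p-values can be too small. Some genes, 37 in number, stand in more than 1 list. The median log2 change of each list was also placed among 10000 random lists matched on 20 bins of mean expression, and 22 lists lay outside the central 95%. Counts adjusted over the list alone used the authors' p-values of the list's tested members.

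The list tests were tested on simulated data in which calls were redrawn over the 10657 tested rows and 4 lists per round were changed. Over 20 rounds, 53 of 53 changed lists with 15 or more tested members and 25 of 27 smaller ones were recovered, and 2 of 748 unchanged list directions were called. Of unchanged lists 3.21% lay outside the central 95% of matched random lists. In the simulation calls were drawn independently for each gene, and unchanged genes were called less often than genes in the data. Most members of a changed list were called, with larger changes than most real lists showed. These rates therefore hold for independent genes and strong changes, and they do not give the error rates for correlated genes.

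Genes are named by a rule fixed beforehand. It takes Spi1, then the 12 largest rises and 12 largest falls among called genes with a finite fold change and at least 5 FPKM in the higher group. It then takes up to 5 called genes per direction that were at 0 in 1 group and at least 5 FPKM in the other, of which there were 0. It adds up to 4 members per list with the smallest q-value (ties by larger absolute fold change, then larger mean) and Igkc, Btk, Blnk, Cd79a, Il7r, Ebf1, Pax5, Rag1, Rag2, Csf1r and Itgam in any case. Some genes that the rule takes are not reported here. Genes named outside this rule were chosen after their values were seen. These are Spib, Rac2, Csf2rb, Fcer1g, Fos, Il2rg, Elane, Ctsg, S100a8, S100a9, Cebpa, Cebpb, Klf4, Cd3e, Cd4, Bcl11b and the genes named only in the closing section.

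Alternatives were other q-value, fold and FPKM limits, recomputed q-values, 1 row per symbol, other scalings, other bins and pseudocounts of 1 and 0.1. P-values from the deposited statistic, leaving out rows that share a locus, the ratio of the value columns, and some settings for the share higher and the lists were added after the data were seen. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.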

Results

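Messenger RNA was sequenced from i660BM cells, a mouse pro-B cell line of C57BL/6 origin that grows in medium with interleukin 7 and carries a doxycycline-inducible PU.1. Pro-B cells are early B cell precursors. PU.1, the product of Spi1, is an ETS family transcription factor that acts in both myeloid and B cells. The 6 libraries fell into 2 groups, 3 from non-induced cells and 3 from cells given 70 ng/ml doxycycline for 48 h. The deposited values were 1 FPKM value per gene and group, a fragment count scaled by transcript length and sequencing depth. They held no value per library, so no standard deviation between libraries is given. The steps between the lowest FPKM values corresponded to about 119000000 fragments for the non-induced group and 120000000 for the induced group, an average of about 39800000 and 40100000 per library.

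The comparison asked which genes changed when PU.1 was induced in pro-B cells. Spi1 itself was the first gene examined, since it checks the group labels. In the authors' deposited table Spi1 stood at 36.0 FPKM in non-induced and 246 FPKM in induced cells, a log2 change of 2.78 with an implied standard error of 0.12 (q = 0.000287). Spi1 lies on the plus strand of chromosome 2 at 91082390 to 91115756 (mm10, a protein-coding gene). The endogenous gene and the introduced copy share this symbol, and the value does not separate them. The value of 36.0 FPKM shows that Spi1 transcripts were present before induction. The related ETS gene Spib was listed at 8.65 and 8.30 FPKM in the authors' deposited table and was not called.

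Induction was accompanied by rises in many, not all, of the tested myeloid receptor, phagocyte oxidase, B cell receptor signalling and interferon response genes. Of the tested members 12 of 21 in glycolysis and hypoxia, 11 of 17 in cholesterol synthesis and 12 of 20 in interleukin 7 signalling were lower, and 4 of the last were higher. The inhibitor of differentiation genes Id1 and Id2 fell. A gene was called when the authors had tested it and their q-value was under 0.05. By that rule 3744 of 10657 tested genes were called (35.1%) in the authors' deposited table, 2023 of them higher and 1721 lower in induced cells. Most changes were small: the median absolute log2 change of the called genes was 0.39, and 2658 of them (71.0%) differed by less than 1.5-fold. At least 2-fold differences were found for 433 called genes, 268 higher and 165 lower. With p-values taken from the deposited test statistic as a normal deviate, 1612 genes were called in place of 3744.

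**Figure D1:**
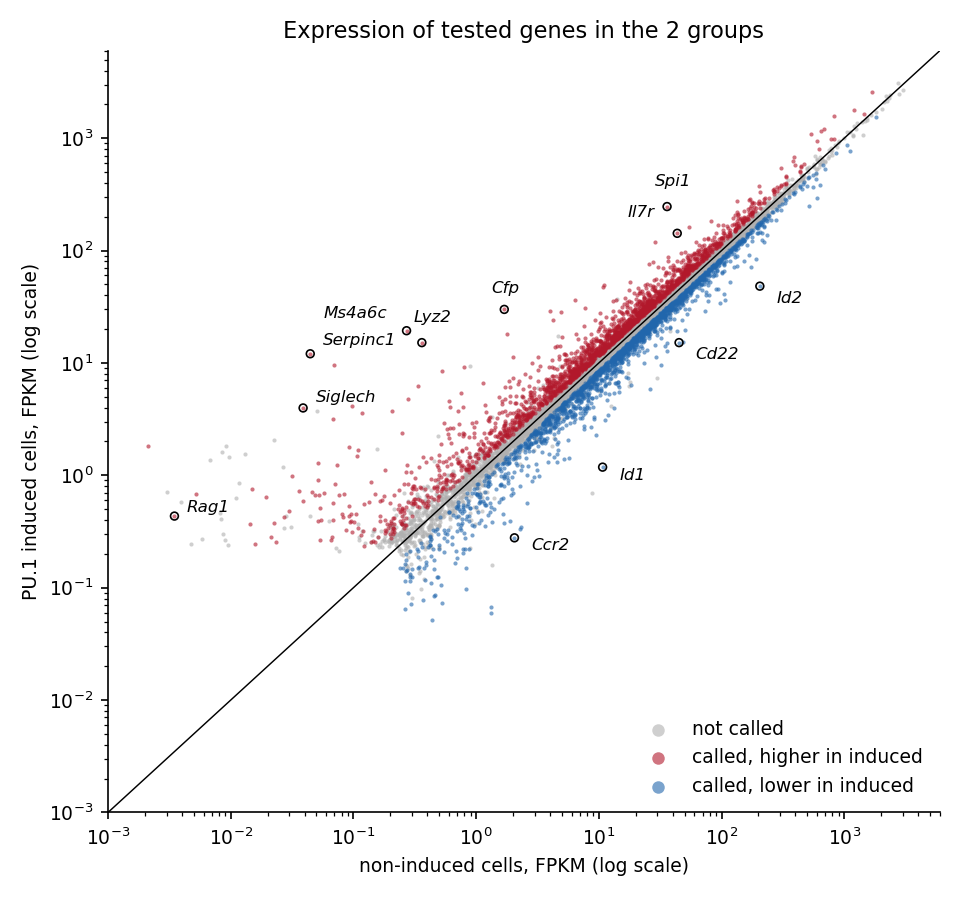
Each point is 1 tested gene with a value above 0 in both groups, with its FPKM in non-induced cells on the horizontal axis and in induced cells on the vertical axis, both on log scales. Called genes are red where higher and blue where lower in induced cells, grey genes were not called, the line marks equal values, and circles mark named genes such as Spi1, which stands at 36.0 against 246 FPKM.

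Slightly more called genes rose than fell. The share that was higher was 54.0% (95% Wilson interval 52.4 to 55.6). By mean FPKM of the groups, a split chosen after the data were seen, it was 60.6% under 1 FPKM (55.6 to 65.4) and 52.7% at 50 FPKM or more (49.0 to 56.4). Genes are not independent, so these intervals describe the counts only. Of the called genes, 22 were listed at 0 in non-induced cells of the authors' deposited table, the highest being Cd33 at 1.99 FPKM in induced cells, and 0 were listed at 0 in induced cells.

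The largest rises among genes reaching 5 FPKM were led by Serpinc1, which encodes antithrombin. In the authors' deposited table it went from 0.0445 to 12.1 FPKM, a log2 change of 8.08 with an implied standard error of 0.70. The unnamed transcript 1700101E01Rik (7.12) and the membrane protein gene Ms4a6c (6.16) followed by log2 change in the authors' deposited table. Lyz2, the lysozyme of macrophages and granulocytes, went from 0.361 to 15.2 FPKM in the authors' deposited table (log2 5.39, implied standard error 0.35). The authors' deposited table gave log2 changes of 4.21 for Oas2, an antiviral oligoadenylate synthetase, 4.14 for Cfp, the complement regulator properdin, and 3.53 for Csf2rb2, a cytokine receptor chain. Spp1, which encodes osteopontin, went from 0.524 to 8.41 FPKM in the authors' deposited table. Adssl1 (3.33), Zeb2os (2.86), Prodh (2.84) and Spi1 completed the 12 largest rises in the authors' deposited table. Zeb2os is annotated as antisense to Zeb2 and shares a locus with it in the table, so its fragments and those of Zeb2 cannot be told apart with certainty.

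The largest fall was that of Id1, and Serpinb1a and Id2 followed. Id1 and Id2 belong to the Id family, inhibitors of basic helix-loop-helix transcription factors. Id1 went from 10.7 to 1.18 FPKM (log2 -3.18, implied standard error 0.21) and Id2 from 205 to 48.2 FPKM (log2 -2.09, implied standard error 0.13) in the authors' deposited table. Serpinb1a, a neutrophil elastase inhibitor, had a log2 change of -2.15 and the Notch target Hes1 one of -1.98 in the authors' deposited table. The chemokine receptor gene Cxcr5 went from 32.0 to 9.56 FPKM in the authors' deposited table (log2 -1.74). The other 7 of the 12 were Slco1a5 (-2.05), Rapgef3 (-1.89), Gimap3 (-1.86), Sema7a (-1.80), Trpm1 (-1.75), Cd248 (-1.68) and Csrp3 (-1.66), as log2 changes in the authors' deposited table.

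**Figure D2:**
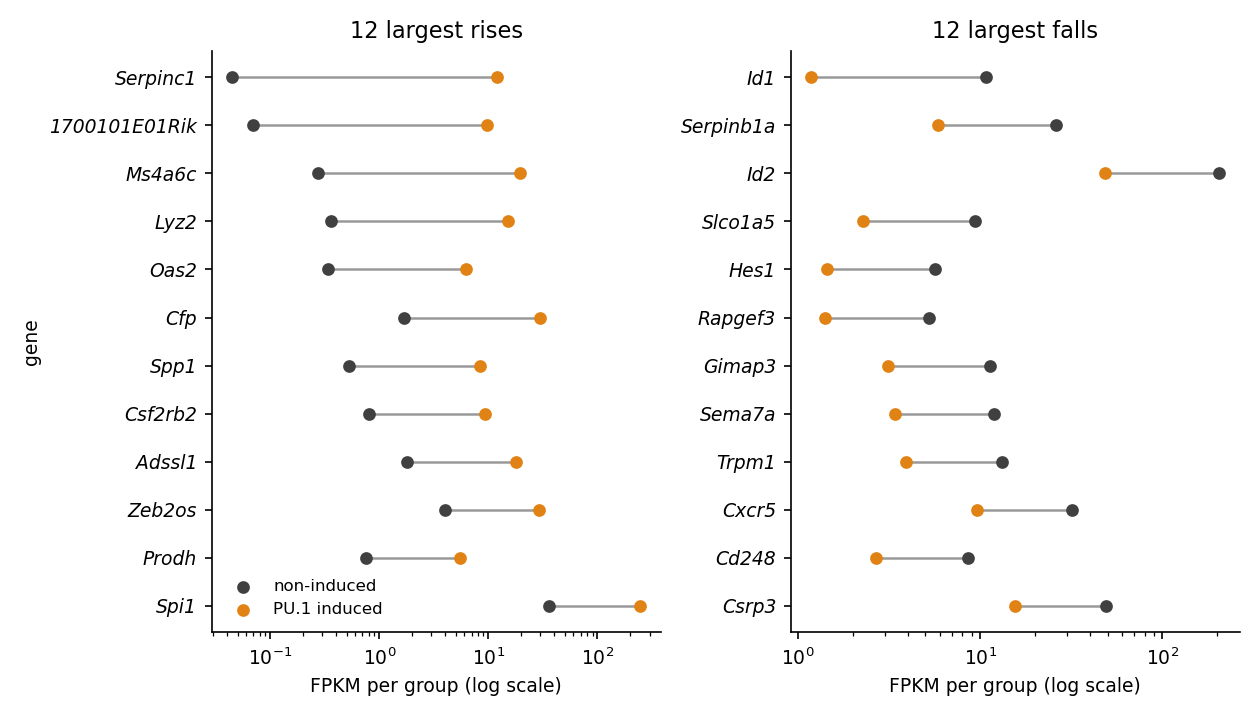
FPKM per group, on a log scale, of the 12 called genes with the largest rise and the 12 with the largest fall among genes of at least 5 FPKM in the higher group. Dark points are non-induced and orange points induced cells; Serpinc1 went from 0.0445 to 12.1 FPKM and Id1 from 10.7 to 1.18 FPKM, and no error bars are drawn because there is 1 value per group.

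Some myeloid genes rose from near 0 and others from higher levels, such as Rac2 (171 to 285 FPKM) and Csf2rb (23.7 to 35.7 FPKM) in the authors' deposited table. Only part of the listed myeloid genes was tested, and untested values at or near 0 can be failed estimates, so they do not show absence. Among 8 tested myeloid receptors and adaptors, 6 were called higher and 1 lower (two-sided Fisher's exact test against the other tested genes, adjusted p = 0.00366). The 1 lower member was Fcer1g, which fell from 69.1 to 44.7 FPKM in the authors' deposited table. The other 12 of the 20 listed were not tested. Members near 0 in non-induced cells could be tested mainly where they rose, so this share and its p-value are tilted toward rises. Among all tested genes under 1 FPKM in non-induced cells, 294 of 1025 were called higher and 117 lower. Cd33, the lipopolysaccharide co-receptor Cd14 and the adaptor Tyrobp were listed at 0 in non-induced cells and at 1.99, 0.995 and 0.334 FPKM in induced cells in the authors' deposited table. The phagocyte NADPH oxidase, the enzyme of the oxidative burst, had 4 of 6 tested members higher and 1 lower (exact test, adjusted p = 0.0383, or 0.0523 without genes that share a locus). Its catalytic subunit Cybb went from 0.0510 to 1.29 FPKM and Ncf1 from 0.0703 to 0.836 FPKM, whereas Ncf4 fell from 41.0 to 24.6 FPKM, in the authors' deposited table.

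Of 24 macrophage and granulocyte markers in the table, 6 were tested, and 5 of these were higher and 0 lower (exact test, adjusted p = 0.00461). As for the receptors, markers near 0 in non-induced cells could be tested mainly where they rose, which tilts this share and its p-value toward rises. Lyz2, Mpeg1 (0.0514 to 0.907 FPKM), Spp1 (0.524 to 8.41 FPKM) and Cd68 (1.85 to 6.86 FPKM) were among them in the authors' deposited table. Of the 23 markers other than Lyz2, 18 were under 0.1 FPKM in induced cells. The granule genes Elane and Ctsg and the calgranulins S100a8 and S100a9 were listed at 0 in both groups. Csf1r, the receptor for macrophage colony-stimulating factor, and Itgam, which encodes CD11b, were not tested by the authors. In the authors' deposited table Csf1r was listed at 0 in non-induced and 0.192 FPKM in induced cells. Itgam was listed at 0.0133 and 0.151 FPKM there. Among 9 tested myeloid transcription factors 1 was higher and 5 were lower (exact test, adjusted p for lower = 0.0224), an excess no longer past 0.05 over genes of at least 1 FPKM (adjusted p = 0.0578). Zeb2 rose from 6.48 to 18.1 FPKM, and Egr1 (77.3 to 35.3 FPKM), Egr2 (0.482 to 0.126 FPKM) and Id2 fell in the authors' deposited table. Of the 5 lower members, Egr1 and Fos also stand in the immediate early and heat shock list, so the tests of these lists are not independent. Cebpa, Cebpb and Klf4 were listed at 0 in both groups. Adjusted over the list alone, the called genes numbered 6 higher and 1 lower for receptors, 4 and 1 for the oxidase, 5 and 0 for markers and 1 and 5 for transcription factors.

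Many B lineage genes also rose. Of 18 B lineage transcription factors, all tested, 11 were higher and 3 lower (exact test, adjusted p = 0.000551; 11 and 3 adjusted over the list alone). Bach2 (log2 0.75), Myb (0.71), Foxo1 (0.58), Ebf1 (0.42) and Pax5 (0.38) rose and Irf4 (-0.68) and Ets1 (-0.54) fell in the authors' deposited table. No member of this list rose by 2-fold, and 2 rose by 1.5-fold or more, which was no excess (exact test, adjusted p = 0.661). Among 16 tested ETS family factors, 8 were higher, Spi1 among them, and 1 was lower (exact test, adjusted p = 0.0162; 9 and 1 adjusted over the list alone). Spi1 was the induced gene, so its rise was set by the design, and no test without it was made. Erg rose from 21.1 to 35.7 FPKM and Etv5 from 0.821 to 1.15 FPKM in the authors' deposited table. The excess in the ETS list was lost with normal p-values from the test statistic (exact test, adjusted p = 0.824), over genes of at least 5 FPKM (0.0643) and without genes that share a locus (0.0778).

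Pre-B cell receptor and recombination genes had 9 of 15 tested members higher and 1 lower (exact test, adjusted p = 0.00245; 10 and 1 adjusted over the list alone). The surrogate light chain gene Igll1 went from 538 to 1083 FPKM, Vpreb3 from 831 to 1566 FPKM and Dntt, the terminal transferase that adds untemplated bases at joins, from 2.24 to 6.90 FPKM in the authors' deposited table. The nuclease gene Dclre1c, which encodes Artemis, went from 4.54 to 8.81 FPKM in the authors' deposited table. The recombinase gene Rag1 was called, at 0.00348 against 0.434 FPKM (log2 6.96, implied standard error 1.45, q = 0.0102) in the authors' deposited table. Its neighbour Rag2, at 0.00853 against 1.60 FPKM, was not called (q = 0.181) in the authors' deposited table and shares a locus with another row there; with normal p-values from the test statistic it was called. Cd79a, a signalling chain of the receptor, stood at 596 and 646 FPKM and was not called (q = 0.283) in the authors' deposited table. Immunoglobulin light chain genes, Igkc included, were not analysed here.

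B cell receptor signalling had 19 of 27 tested members higher and 4 lower (exact test, adjusted p = 2.17e-07; 19 and 4 adjusted over the list alone). The inhibitory Fc receptor gene Fcgr2b went from 4.25 to 24.1 FPKM, the kinase gene Syk from 25.5 to 76.2 FPKM and the adaptor gene Pik3ap1 from 27.4 to 79.9 FPKM in the authors' deposited table. Btk (log2 0.38) and Blnk (0.51) rose by less, and the inhibitory receptor gene Cd22 fell from 45.0 to 15.2 FPKM, in the authors' deposited table. Of 21 tested genes described as regulated by PU.1 or SPI-B in B cells, 15 were higher and 3 lower (exact test, adjusted p = 4.21e-06; 15 and 3 adjusted over the list alone). That list was drawn from general knowledge and shares members such as Syk, Fcgr2b, Btk, Blnk and Cd22 with the signalling list, so the tests are not independent. Among 11 tested markers of mature and immature B cells 5 were higher and 3 lower (5 and 3 adjusted over the list alone), with no excess in either direction (exact test, adjusted p = 0.0791 and 0.595), but an excess of higher members with normal p-values (adjusted p = 0.0318). Bst1 (log2 0.84), Il2ra (0.70), Spn (0.61) and Cd24a (0.56) rose in the authors' deposited table. Plasma cell markers had 4 of 7 tested members lower and 1 higher (exact test, adjusted p for lower = 0.0389; 5 and 1 adjusted over the list alone). Ell2 (log2 -0.99), Irf4, Xbp1 (-0.50) and Sdc1 (-0.38) fell in the authors' deposited table, and the excess was lost without genes that share a locus (adjusted p = 0.0594).

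Genes of interleukin 7 signalling had an excess of falls, while the receptor gene Il7r rose. Il7r went from 43.5 to 142 FPKM (log2 1.71, implied standard error 0.15) in the authors' deposited table. Il2rg, which encodes the other chain of the receptor, fell from 75.8 to 52.2 FPKM there. Of the 20 tested members 12 were lower and 4 higher (exact test, adjusted p for lower = 9.26e-05; 13 and 4 adjusted over the list alone). The feedback inhibitor gene Cish went from 117 to 53.1 FPKM, the survival gene Bcl2 from 13.9 to 6.64 FPKM and the kinase gene Pim2 from 93.0 to 45.6 FPKM in the authors' deposited table.

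S phase and mitosis genes had an excess of small rises. Of 24 S phase genes, all tested, 16 were higher and 0 lower (exact test, adjusted p = 5.45e-06; 18 and 0 adjusted over the list alone). Uhrf1 (log2 0.63), the origin licensing gene Cdt1 (0.53), Rrm2 (0.44) and Cdc6 (0.39) had the largest rises among members sharing the smallest q-value in the authors' deposited table. Of 24 mitosis genes, all tested, 12 were higher and 0 lower (exact test, adjusted p = 0.00255; 13 and 0 adjusted over the list alone), with Nusap1 (log2 0.51), Cenpa (0.41), Mki67 (0.34) and Ccna2 (0.33) as examples from the authors' deposited table. With normal p-values from the test statistic the calls numbered 3 of 24 S phase and 2 of 24 mitosis genes, and neither list kept its excess (exact test, adjusted p = 0.679 and 1), nor at 1.5-fold (1 and 0 members higher). Among 20 tested cell cycle inhibitors and p53 targets, 9 were higher and 4 lower (exact test, adjusted p = 0.0213; 9 and 5 adjusted over the list alone), with a median log2 change at percentile 97.0 of expression-matched random lists, inside their central 95%. The excess was lost over genes of at least 5 FPKM (6 higher; exact test, adjusted p = 0.098) and at 2-fold (adjusted p = 0.289). Btg2 (log2 1.99), Tnfrsf10b (1.60) and Cdkn1b (0.97), which encodes p27, rose and Cdkn2b (-0.87) fell in the authors' deposited table.

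Many innate immune genes rose as well. Of 28 tested interferon response genes, 23 were higher and 1 lower (exact test, adjusted p = 4.32e-11; 23 and 1 adjusted over the list alone). Oas2 went from 0.335 to 6.20 FPKM, Oas3 from 0.0512 to 0.394 FPKM, Ifit3 from 0.169 to 0.597 FPKM and Mx2 from 0.392 to 1.32 FPKM in the authors' deposited table. Toll-like receptor and NF-kB genes had 9 of 18 tested members higher and 1 lower (exact test, adjusted p = 0.0101; 9 and 1 adjusted over the list alone). Tlr9, a receptor for unmethylated DNA, went from 2.51 to 7.97 FPKM and Unc93b1, which traffics it, from 81.4 to 182 FPKM in the authors' deposited table. Tnfaip3 rose (log2 0.88) and the adaptor gene Tirap fell (-1.06) in the authors' deposited table. The excess in the Toll-like receptor and NF-kB list was kept at 1.5-fold (6 higher, exact test, adjusted p = 0.00289) and lost at 2-fold (2 higher, adjusted p = 0.257). No library received doxycycline without PU.1 induction, so the drug and the induced factor vary together in every comparison given here.

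Lysosome and cathepsin genes had 12 of 20 tested members higher and 1 lower (exact test, adjusted p = 0.00038; 12 and 1 adjusted over the list alone). Lgmn (log2 1.65), Asah1 (0.88) and Grn (0.76) were among those with the smallest q-values in the authors' deposited table. The excess in this list was kept at 1.5-fold (6 higher, exact test, adjusted p = 0.00465) and lost at 2-fold (1 higher, adjusted p = 0.865). Integrin and chemokine receptor genes went both ways, with 6 of 15 tested members higher and 6 lower (exact test, adjusted p = 0.0905 and 0.05, the latter just under the threshold; 6 and 6 adjusted over the list alone). The median log2 change of this list lay at percentile 57.5 of expression-matched random lists. The chemokine receptor gene Ccr2 fell from 2.05 to 0.278 FPKM in the authors' deposited table. Both directions passed the threshold at q under 0.01 (exact test, adjusted p = 0.0367 for higher and 0.0132 for lower), whereas over genes of at least 1 FPKM the lower members did not (adjusted p = 0.0884). MHC class II had 2 of 7 tested members higher and 3 lower (2 and 3 adjusted over the list alone), with no excess in either direction (exact test, adjusted p = 0.792 and 0.149), although its median log2 change of -0.39 lay at percentile 0.545 of expression-matched random lists. At 2-fold its 2 lower members were an excess (exact test, adjusted p = 0.0225). H2-DMb2 (log2 -1.50) and H2-Eb2 (-1.05) fell and Cd74 (0.59) and H2-Ob (0.30) rose in the authors' deposited table.

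Glycolysis and cholesterol synthesis genes had an excess of modest falls. Of 21 tested glycolysis and hypoxia genes 12 were lower and 0 higher (exact test, adjusted p for lower = 0.000158; 12 and 0 adjusted over the list alone). Eno1 (log2 -0.55), Pfkl (-0.49), Gapdh (-0.47) and Tpi1 (-0.44) fell in the authors' deposited table, and 0 members fell by 1.5-fold or more. Of 17 tested cholesterol synthesis genes 11 were lower and 0 higher (exact test, adjusted p for lower = 9.26e-05; 13 and 0 adjusted over the list alone). Lss (-0.87), Fdps (-0.67) and Mvd (-0.61) were among those with the smallest q-values, as log2 changes in the authors' deposited table. Nuclear-encoded oxidative phosphorylation genes had 1 of 30 tested members higher and 4 lower (1 and 4 adjusted over the list alone), with no excess in either direction (exact test, adjusted p = 0.064 and 0.955). Their median log2 change of -0.13 nonetheless lay at percentile 0.445 of expression-matched random lists. Ndufb8 (log2 0.40) rose and Ndufb3 (-0.27), Ndufs1 (-0.25) and Cyc1 (-0.25) fell in the authors' deposited table. The 21 tested genes of the ATF4 and mitochondrial stress response had 6 higher and 2 lower (6 and 2 adjusted over the list alone; exact test, adjusted p = 0.418 and 0.747). Mthfd2 (log2 0.37), Cebpg (0.29) and Slc7a5 (0.26) rose and Ddit4 (-0.47) fell in the authors' deposited table. Mitochondrially encoded genes were not analysed here.

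Immediate early and heat shock genes had 9 of 16 tested members lower and 2 higher (exact test, adjusted p for lower = 0.00147; 9 and 2 adjusted over the list alone). Egr3 (log2 -1.92), Egr1 (-1.13) and Ier2 (-0.93) fell and Ier3 (1.85) rose in the authors' deposited table.

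**Figure D3:**
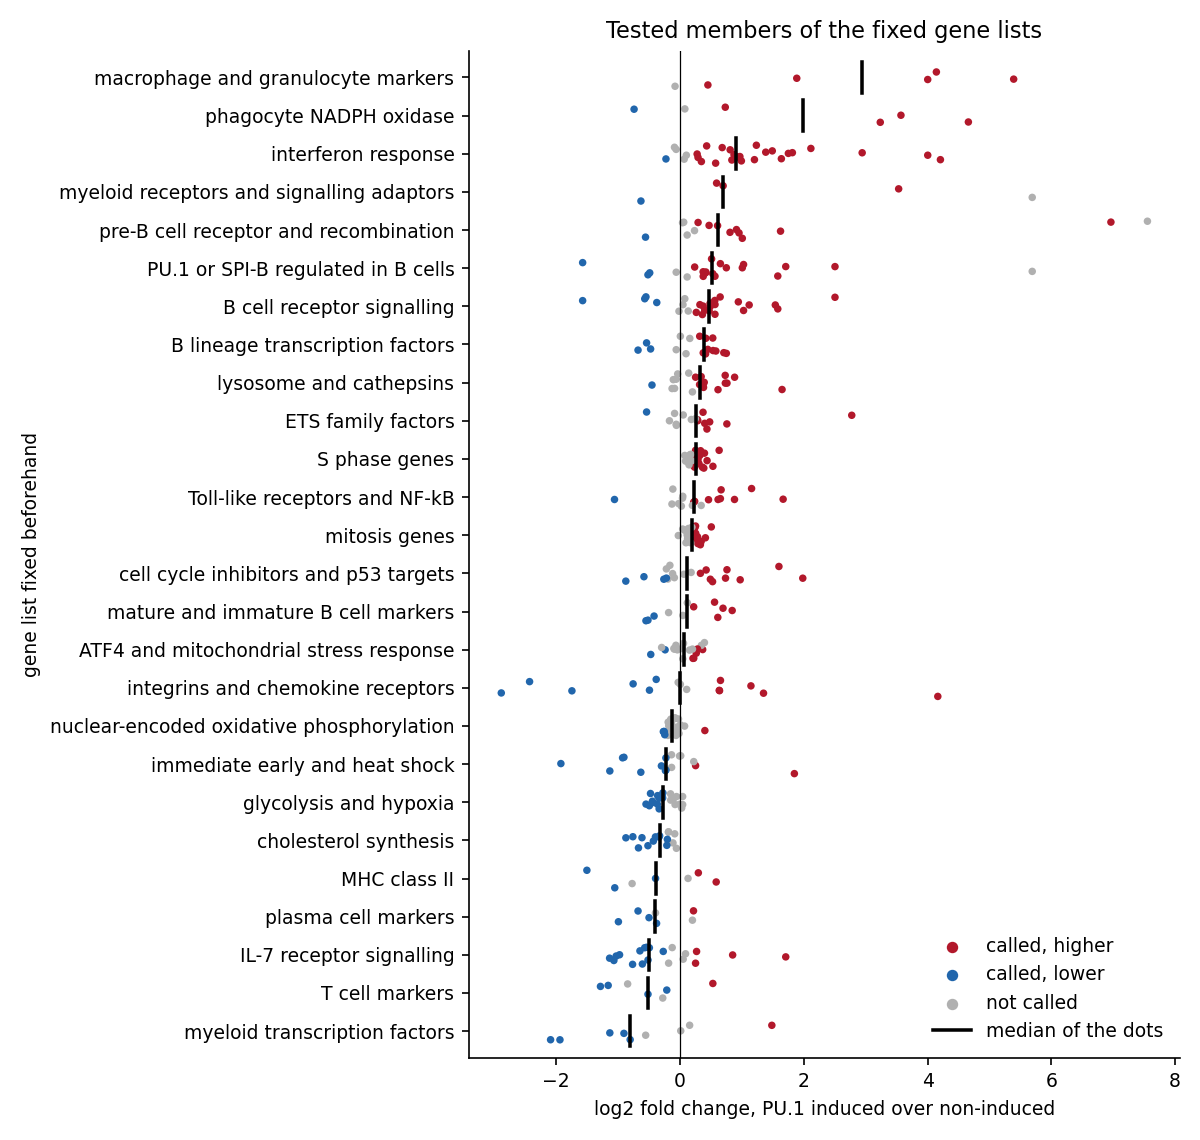
Log2 fold changes (PU.1 induced over non-induced, horizontal axis) of the tested members of each gene list with at least 5 tested members, 1 dot per gene and 1 list per line, ordered by the median of the dots (black bar). Red dots were called higher, blue dots called lower and grey dots not called; genes listed at 0 in 1 group, such as Cd33, have no finite fold change and are not drawn, and 23 of the 28 interferon response genes are red.

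Markers of other cell types were mostly listed near 0 and untested, which does not show that they were absent. T cell markers had 4 of 7 tested members lower and 1 higher (exact test, adjusted p for lower = 0.0389; 5 and 1 adjusted over the list alone), an excess lost at q under 0.01 (adjusted p = 0.0771). Cd28 (34.6 to 14.2 FPKM), Zap70 (43.0 to 19.3 FPKM) and Lck (66.0 to 46.1 FPKM) fell and Cd2 (4.62 to 6.68 FPKM) rose in the authors' deposited table. Cd3e, Cd4 and Bcl11b were listed at 0 in both groups. The remaining 5 lists had too few tested members for a test. NK cell markers had 1 tested member, Klrd1, which rose from 3.76 to 6.67 FPKM in the authors' deposited table. Erythroid and megakaryocyte markers had 2 tested members, of which the globin gene Hbb-bt fell from 1.05 to 0.375 FPKM in the authors' deposited table, while Gp1ba was not called. Mast cell and basophil markers had 0 tested members. Dendritic cell markers had 4, of which Siglech rose from 0.0389 to 3.98 FPKM and Flt3 from 0.308 to 0.759 FPKM in the authors' deposited table, while Bst2 and Tcf4 were not called. Stromal cell markers had 2, Acta2 (0.259 to 0.494 FPKM) and Il7 (0.394 to 0.571 FPKM), and both were higher in the authors' deposited table. Adjusted over the list alone, the counts of these 5 lists were the same as over all genes.

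In all, 26 lists were tested in 52 tests, of which 14 showed an excess of higher and 8 an excess of lower members at an adjusted p under 0.05. The calls rest on the authors' p-values, which were smaller than those of a normal deviate at the same test statistic for 9808 of 10628 tested genes with a finite statistic, though not for many with large statistics. Among the 3722 called genes with a finite statistic, 1213 (32.6%) had a statistic too small for a two-sided normal p-value under 0.05. Genes with a p-value between 0.045 and 0.055 had a median absolute statistic of 1.17.

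**Figure D4:**
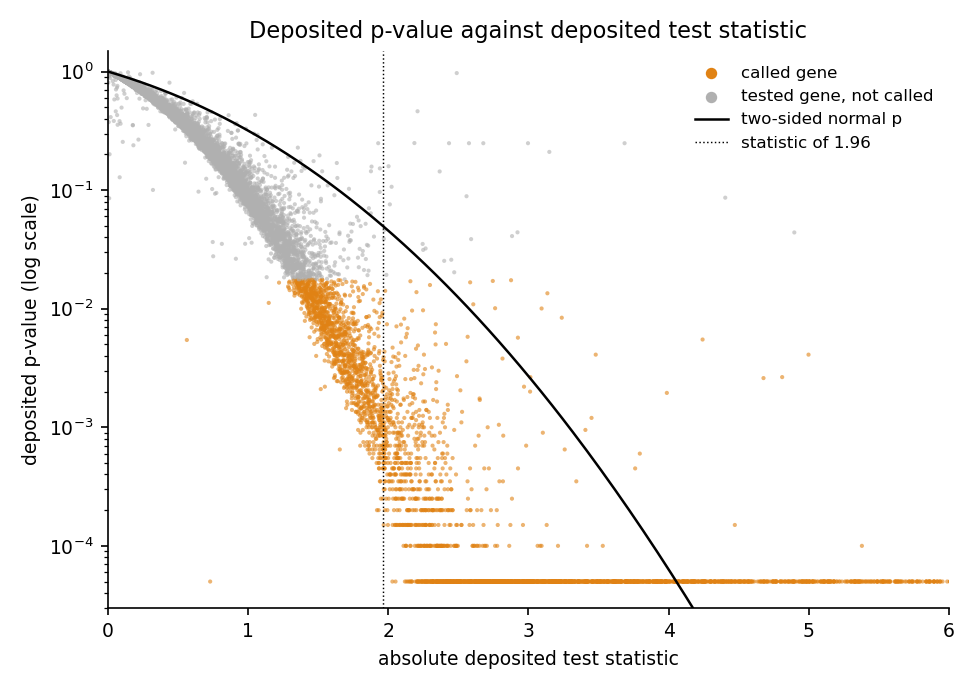
Deposited p-value (vertical, log scale) against the absolute deposited test statistic (horizontal, shown up to 6) for tested genes, with called genes in orange and the others in grey. The black curve is the two-sided normal p-value and the dotted line marks the statistic at which that p-value is 0.05; most points lie below the curve, and 32.6% of called genes with a finite statistic lie left of the dotted line.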

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

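The tests of doxycycline, of myeloid cells in the cultures, of the detection floor and of the spread behind the p-values were chosen after the results were seen; those of counting noise, shared fragments and interferon gene transcription were written before.

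Small RNA genes that the authors did not test had a signal in induced cells and were listed at 0 in non-induced cells. The authors' deposited table gave Snord47 at 497 FPKM, Mir6935 at 472, Snord2 at 325, Mir1982 at 188, Mir677 at 94.7, Snord35a at 26.6 and Mir7-1 at 13.8 FPKM. Another 6 untested genes were listed in the authors' deposited table at 0 in induced cells with at least 5 FPKM in non-induced cells, Mir25 being the highest at 68.1 FPKM. Scaling by transcript length is uncertain for genes this short, and without a test none of these values shows a change.

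Some myeloid genes, such as Cd33, Cybb and Lyz2, rose from near 0. A share of myeloid cells in the induced cultures was considered. The median of the 23 listed macrophage and granulocyte markers other than Lyz2 was 0.00707 FPKM in induced cells, and 11 of them were listed at 0. Values at or near 0 can be failed estimates, and a small share of cells need not bring every marker. Of the 23 markers 18 were under 0.1 FPKM in induced cells, but Spp1 stood at 8.41 and Cd68 at 6.86 FPKM. The median therefore cannot decide this question. Counting noise of a few fragments was examined in the 11 called myeloid genes that started under 1 FPKM. They rested on a median of about 429 fragments in induced and 26.5 in non-induced cells, computed from the shortest annotated transcript. The fewest in induced cells was 22.7. These genes were picked because they were called higher, so very few fragments in induced cells was an unlikely outcome. The counts describe these 11 genes and do not settle the question for the other members. Doxycycline itself stays open, since 0 libraries had the drug without PU.1 induction. A direct or indirect effect of PU.1 is a hypothesis that may account for the rise, and it cannot be told apart from the drug in this design.

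Interferon response genes rose. The rise was not limited to genes near the detection floor, since 10 of the 14 list members of at least 5 FPKM in non-induced cells were called higher (71.4%), with a median log2 change of 0.39 over these 14 against 1.57 over the 14 less abundant ones. Interferon genes were near 0, with 20 of 21 listed at 0 in both groups and the highest, Ifnz, at 0.0191 FPKM in induced cells. Transcription of interferon by the cells at 48 h was thus not detected, but values of 0 can be failed estimates, so it is not excluded. Doxycycline itself stays open for the same reason as above (0 libraries), and interferon made before sampling was not tested.

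Many called genes changed by small amounts. Of the called genes with a finite statistic, 32.6% had a statistic too small for a two-sided normal p-value under 0.05. Whether the p-values rest on too small a spread between libraries cannot be told without values per library. Fragments shared between overlapping genes do not account for the number of calls: genes that share a locus were called less often (24.2% of 2244) than others (38.1% of 8413), an odds ratio of 0.518 (95% interval 0.465 to 0.577).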

How the results depend on the processing

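Normal p-values, leaving out rows sharing a locus, the ratio of the value columns, lists at 2-fold, at 5 FPKM and at q under 0.1, and the share higher at 1.5-fold and at q under 0.1 were added after the data were seen. No paired analysis was possible because the table holds group values only, although the labels number the libraries 1 to 3 in both groups. For the same reason leaving out replicates, other splits of the libraries, an estimated correlation, a per-library filter or pseudocount and DESeq2 were not run. Of 3744 genes called, 1086 were left at 1.5-fold and 433 at 2-fold, by construction of the limit. Normal p-values from the test statistic called 1612 genes, 1602 of them shared with the 3744, and 1620 after centring; the normal p-value was the larger for 9808 of 10628 genes. The other settings gave between 2759 (q under 0.01) and 4343 (q under 0.1). The share of called genes that were higher, 54.0%, moved to 57.0% at q under 0.01, 52.3% at q under 0.1, 62.2% at 1.5-fold, 61.9% at 2-fold, 59.3% with normal p-values and 62.0% with these after centring; the cause was not tested. The upper quartile and median shifts taken out of the log2 changes, -0.0075 and -0.0154, were smaller than any called change, so these settings could not alter the calls. Of the 22 list directions in excess, 21 were kept at q under 0.01 and at q under 0.1. At 1.5-fold 15 were kept, with normal p-values 19 and without rows sharing a locus 17. Over genes of at least 1 FPKM 18 were kept and 2 lost, and the oxidase and macrophage lists had too few tested members. Over genes of at least 5 FPKM 15 were kept and 3 lost. There the myeloid receptor, oxidase, macrophage and plasma cell lists had too few tested members, so their excess could not be checked. At 2-fold, 13 were in excess, 11 of them among the 22, with fewer genes called. For Spi1 and the other named genes with a finite fold change, 128 in all, a pseudocount cannot reverse a direction, so only sizes were compared. A pseudocount of 1 shrank 33 of these log2 changes by more than 1.5 times, as it does by construction for genes near or under 1 FPKM, whose fold changes are also the least certain at this depth.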

Other observations

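The tests of symbol families and the genes named here were chosen after the data were seen, and the tests of neighbouring genes were written before their results.

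Replication-dependent histone genes went against the S phase list. Of 40 tested Hist1h genes, 19 were lower and 0 higher (two-sided Fisher's exact test, adjusted p for lower = 0.00061 over 88 symbol families and both directions), with a median log2 change of -0.58. Hist1h4d went from 9.47 to 4.99 FPKM and Hist1h3c from 11.6 to 7.82 FPKM in the authors' deposited table. These genes have near-identical copies and mostly lack poly(A) tails, so their values in an mRNA library are uncertain. The Gimap genes, GTPases of lymphocytes on chromosome 6, had 7 of 8 tested members lower and 0 higher (exact test, adjusted p = 0.00171). Gimap7 went from 5.68 to 3.46 FPKM and Gimap8 from 9.54 to 5.91 FPKM in the authors' deposited table. Mitochondrial ribosomal protein genes of the Mrpl family had 0 of 46 tested members higher and 7 lower (exact test, adjusted p for the shortage of higher members = 0.00548). In the Id family, Id3 was also lower, at 205 and 148 FPKM in the authors' deposited table, alongside Id1 and Id2.

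Further rises from low levels belonged to no fixed list. In the authors' deposited table Gas7 went from 0.0968 to 4.16 FPKM, Itgb4 from 0.117 to 3.60 FPKM, Fcrla from 0.616 to 4.09 FPKM and Gsn from 0.777 to 4.06 FPKM. Epha2 and Cyp27a1 were listed at 0 in non-induced and at 1.33 and 1.33 FPKM in induced cells in the authors' deposited table.

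Called genes that neighbour each other tended to change in the same direction. Of 1456 pairs of adjacent tested genes that were both called, 61.7% shared a direction, against 47.7 to 52.9% in the central 95% of 10000 shuffles of the directions (one-sided permutation p = 0.0001, the smallest these shuffles can give). With pairs that share a locus left out the share was 61.5% of 1433 pairs (one-sided permutation p = 0.0001), so fragments shared within a locus do not account for it. Leaving out also the Hist, Gimap, Ms4a, Ifi and Gbp families gave 61.1% of 1398 pairs.

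Ptprc, which encodes CD45, was not tested and stood at 0.00608 and 0.0649 FPKM in the authors' deposited table, while the leukocyte genes Laptm5 (204 and 332 FPKM), Cd52 (152 and 226 FPKM) and Coro1a (432 and 515 FPKM) were abundant. Ppia and Ftl1, which have near-identical copies, stood at 0.744 and 0.747 FPKM in non-induced cells in the authors' deposited table. The microRNA genes Mir682 and Mir2137 stood above 1000 FPKM in both groups of the authors' deposited table and were not called.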
